A study of Mus musculus with 11 samples.

How the data were processed

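Poly-A RNA from the mandibular condylar fibrocartilage of ovariectomized female mice was sequenced in 11 samples, each a separate sample in the labels. Genotype (wild type, WT, or an estrogen receptor alpha knockout, ERalphaKO, written KO) and agent (placebo, or a slow-release pellet of 17β-estradiol) gave 4 groups, with 2 WT placebo samples and 3 in each other group. The labels give replicate numbers but do not say that each sample is a different animal, so the p-values measure the spread between these samples, which may be technical in part.

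Per the submitters' processing notes, bcl2fastq 2.17, TopHat and the mouse build mm9 were used. The program and annotation that assigned reads to genes, and whether strand was used, are not given in the sources used here. The deposited count table holds raw whole-number counts for 23420 gene symbols, 1 column per sample, and 0 columns were left unmapped to a sample. The authors also deposited 6 tables of pairwise comparisons, which per the file headers have the columns of DESeq2 output. The authors' effects are log2 fold changes of 1 group over the other with standard errors, per the file headers. A test score, whose formula the headers do not give, and raw and adjusted p-values stand beside them, also per the file headers. From the authors' deposited tables, only the numbers of genes with an adjusted p-value under 0.05 are quoted, and each such sentence names its source.

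Totals ran from 15.7 to 25.5 M counts per sample. At these depths a level of 3 counts, used here as the floor per library, equals 0.118 to 0.204 CPM, the count per M of the scaled library total. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Of the 23420 symbols, 5218 had no count in any sample and 27 had been turned into dates by a spreadsheet, as the values show, and these were left as they stand. No 2 libraries of the same group matched within sampling noise. Genes that share reads with near-identical copies, overlapping genes and antisense pairs remain uncertain, since the counting method is unknown.

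All values below were computed from the counts. In R 4.3.3, edgeR 4.0.16 filtered genes with filterByExpr (a count of at least 10 in enough samples and at least 15 in total), which kept 14531 genes holding 99.98% of counts. Library sizes were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to the 4 groups over all 11 samples, so that the groups share 1 estimate of spread with 7 residual degrees of freedom. The common coefficient of biological variation was 15.8%. Every adjusted p given for a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14531 genes of that comparison, and a gene was called at an adjusted p-value under 0.05. Standard errors (SE) were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled group means ± SD over the samples of a group. Where a group had 0 counts of a gene, its fold is a bound against 3 counts per library. Where it had 1 to 3 counts in all, the ratio is given with its exact 95% counting interval.

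There were 6 comparisons: estradiol against placebo in WT, the same in KO, the difference between these effects (interaction, WT effect minus KO effect), KO against WT under placebo, KO against WT under estradiol, and KO against WT averaged over both agents. A total of 28 gene lists, covering cartilage, bone, matrix, signalling and cell cycle genes and markers of other cell types, were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Each list was also tested with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its genes move, on balance, in 1 direction. Beside a camera p, the same paragraph gives the p with an estimated correlation, or its range over several lists. Beside the members called over all genes stands the number called when p-values were adjusted over the list alone, where it differs. Summed CPM of a list is given where many members had 0 counts.

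Named genes followed a rule. It took up to 8 called genes with the largest rise and 8 with the largest fall in each comparison, with a mean CPM of at least 1 and no overlap between the samples compared. The overlap condition was dropped for the interaction and for the average, and predicted genes, immunoglobulin and T cell receptor families and small RNAs were left out. The rule added up to 4 members with the smallest p of each list that passed, and 16 genes of the receptor, cartilage and growth that were always to be reported. Where fewer than 5 genes passed, the 5 with the smallest p were named. Groups, tests, gene lists, the naming rule and all alternatives but those named as added were fixed before the data were examined.

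The alternatives were an adjusted p under 0.1, at least a 2-fold change, RLE or upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter at a mean CPM of 1, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. After the data were seen, fits without the ribosomal precursor Rn45s and without WT placebo 2 and KO placebo 1 together were added. Whether the replicate numbers pair samples was checked by the correlation of deviations from the group means. Over all groups 7 of 15 same-number pairs exceeded 0.1 (range -0.20 to 0.39), against 3 of 30 other pairs. Deviations sum to 0 within a group, so the 2 WT placebo samples mirror each other and these pairs are not independent. The 2 counts therefore only describe the samples. All 3 same-number pairs of KO placebo and KO estradiol samples exceeded 0.1 (0.290, 0.386 and 0.142). The value with the block is therefore given beside the estradiol result in KO. The labels state no pairing, and it was read from the same counts that the block was fitted to. Counts with the block are thus no independent evidence. In WT the same-number pairs of placebo and estradiol samples correlated at -0.203 and -0.159. When a library of the WT placebo group was left out, the lone sample was assumed to vary like the other groups. The gene tests and list tests were run on simulated counts for 14531 genes, with 200 genes changed and the 40 cell cycle genes also raised 1.5-fold. In each comparison the cell cycle list passed by camera and 0 other lists did. Genes were drawn independently, so the simulation cannot judge the list tests where genes move together. Of the 200 genes, changed 1.5-, 2- or 4-fold, the estradiol comparison in WT recovered 32.8%, 70.1% and 89.4% by size of change. That in KO recovered 46.3%, 91.0% and 98.5%, and the interaction 5.97%, 55.2% and 86.4%. The genotype comparison recovered 25.4%, 77.6% and 90.9% under placebo, 40.3%, 73.1% and 97.0% under estradiol, and 74.6%, 88.1% and 93.9% averaged. False calls, those outside the 200 and the cell cycle genes, made up 3.38% to 8.19% of calls across these comparisons.

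Gene positions relative to Esr1 were taken from a GRCm38.p6 gene table, which differs from mm9, so it served only for neighbourhood. It matched 13566 of the 14531 tested genes (93.4%). Tables and plots were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.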

Results

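Gene expression in the condylar fibrocartilage of the mouse jaw joint was measured by RNA sequencing in ovariectomized females with and without estrogen receptor alpha. Surgery was done at 6 weeks of age, a placebo or 17β-estradiol pellet (0.01 mg, made to release over 60 days) was given for 1 week, and tissue was taken at 7 weeks. The WT placebo group had 2 samples and the WT estradiol, KO placebo and KO estradiol groups had 3 each. WT placebo samples 1 and 2 held 19.3 and 16.5 M counts, and WT estradiol samples 1 to 3 held 25.5, 21.5 and 23.1 M. KO placebo samples held 23.5, 21.1 and 24.0 M, and KO estradiol samples 17.9, 15.7 and 21.8 M. In WT placebo 2 the ribosomal precursor Rn45s took 16.04% of counts, against 1.83% to 3.13% in the other libraries. All RNA of the dissected tissue was sequenced together, so marker genes of muscle, blood and vessels were measured along with those of cartilage.

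Esr1, which encodes estrogen receptor alpha, was lower in every KO library than in any WT library. Its level was 13.4 and 6.60 CPM in the 2 WT placebo libraries, 7.03 ± 0.77 in WT estradiol (n = 3), 3.84 ± 1.1 in KO placebo (n = 3) and 3.24 ± 0.62 in KO estradiol (n = 3). WT libraries held 97 to 249 Esr1 counts and KO libraries 43 to 115. Averaged over both agents the log2 difference between KO and WT was -1.25 (SE 0.21, adjusted p = 0.00478). Under placebo it was -1.39 (SE 0.30) and did not pass (adjusted p = 0.468). These are counts over the whole gene, and the deleted part is not visible in them, so the lower level does not show how much receptor remains. Esr2, the gene of estrogen receptor beta, had 0 to 5 counts per library, too few to be tested.

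**Figure D1:**
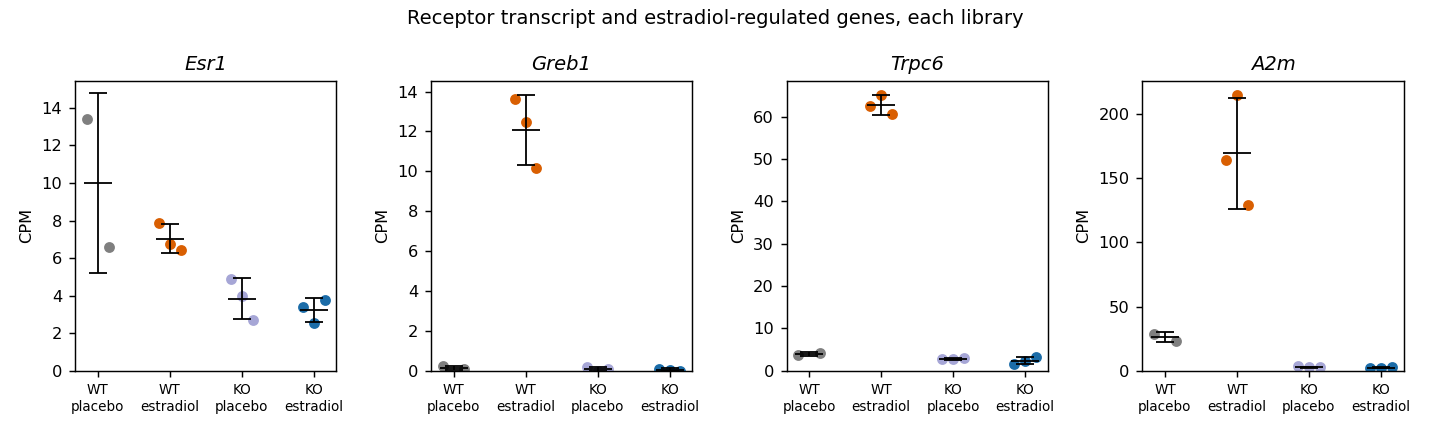
Expression in CPM (vertical axis) of Esr1, Greb1, Trpc6 and A2m in each of the 4 groups, with 1 point per library and lines for the group mean ± SD. Trpc6 lies at 62.8 CPM in WT estradiol and at 2.35 to 3.97 CPM in the other groups.

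The effect of estradiol in animals with the receptor was asked first. In WT tissue estradiol raised 95 genes in edgeR, some of them from under 1 CPM. Greb1, a classical estrogen receptor target, went from 0.142 ± 0.10 CPM (n = 2) to 12.1 ± 1.7 CPM (n = 3), a 78.0-fold rise (log2 6.28, SE 0.57, adjusted p = 0.000119). Trpc6, a calcium-permeable channel, rose 15.8-fold from 3.97 ± 0.44 to 62.8 ± 2.3 CPM (adjusted p = 9.87e-07). Lgi2 rose from 0.371 to 15.9 CPM (log2 5.34, SE 0.40, adjusted p = 4.08e-05), and Asb4 from 0.183 to 9.89 CPM (log2 5.73, SE 0.51). Shank2, Myo5c and Pi15 rose by 4.22, 4.11 and 3.69 on the log2 scale. Sftpa1, a surfactant protein gene, had 1 count in WT placebo and 11.3 ± 2.6 CPM after estradiol, a ratio of 372 with a 95% counting interval of 66.5 to 14699. A2m, a secreted protease inhibitor that lies outside the naming rule here and was chosen after its values were seen, went from 26.1 ± 4.0 to 170 ± 43 CPM (log2 2.70, SE 0.22, adjusted p = 0.000109).

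Genes of bone and growth signalling also moved in WT. Igf1, the main local growth factor of the growth hormone axis, fell 2.38-fold from 150 ± 6.7 to 63.0 ± 18 CPM (adjusted p = 0.00688). It was the 1 member of 17 tested in the growth hormone and IGF list that fell over all genes, while 1 member was higher and 4 were lower when adjusted over the list alone. The list ranked below other genes (camera adjusted p = 0.0216, adjusted p = 0.433 with an estimated correlation). In the Wnt list, Wnt4 (40.0 to 89.7 CPM, log2 1.17, SE 0.10) and Sost, an osteocyte inhibitor of Wnt signalling (40.7 to 101 CPM, log2 1.32, SE 0.15), rose, while Wif1 and Wnt16 fell by 0.62 and 1.86 on the log2 scale, among 28 tested, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0392 downward, adjusted p = 0.433 with an estimated correlation). Lox, which crosslinks collagen, rose from 487 to 858 CPM (log2 0.82, SE 0.12) as the 1 called gene of 23 in the collagen processing list, with 2 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.661 with an estimated correlation). Lum fell by 0.50 on the log2 scale (SE 0.11) as the 1 called gene of 26 in the fibrous matrix list, with 3 adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.523 with an estimated correlation). The list of estrogen-responsive genes from other tissues had Greb1 and Wnt4 up and Igf1 and Cxcl12 down among 23 tested, with 3 higher and 4 lower adjusted over the list alone, and as a list it did not pass (camera adjusted p = 0.517, adjusted p = 0.661 with an estimated correlation). Its member Cxcl12, a chemokine named because the called members are few, stood at log2 -2.14 (SE 0.24, adjusted p = 0.00139). In the cartilage and hypertrophic lists 1 gene each was called, Matn4 at log2 -1.33 (adjusted p = 0.00226) and Ibsp at log2 0.68 (adjusted p = 0.0298), both chosen after their values were seen and not followed through the alternatives. Col2a1, Acan, Sox9, Col10a1 and Ihh did not pass. Pgr, another receptor target, stood at 0.0808 and 0.565 CPM (adjusted p = 0.308).

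Lists of markers of other cells were tested alongside. Of 16 B cell lineage genes, 7 fell and 13 passed when adjusted over the list alone, and the list ranked lower (camera adjusted p = 2.42e-07, adjusted p = 0.433 with an estimated correlation). Vpreb3, a member of that list, went from 5.31 to 0.175 CPM (log2 -4.93, SE 0.58), and summed B lineage CPM from 81.6 ± 5.8 to 26.3 ± 2.3. Summed neutrophil lineage CPM was 371 ± 202 under placebo and 22.2 ± 21 after estradiol, with 0 of 15 members called over all genes in edgeR and 6 adjusted over the list alone (camera adjusted p = 2e-05, adjusted p = 0.59 with an estimated correlation). Osteoclast markers ranked higher, with 2 of 15 called (Acp5 from 3515 to 5372 CPM, and Ocstamp) and 6 adjusted over the list alone (camera adjusted p = 1.05e-07, adjusted p = 0.433 with an estimated correlation). Macrophage genes had 0 of 15 called and 5 adjusted over the list alone (camera adjusted p = 8.71e-05 upward, adjusted p = 0.433 with an estimated correlation). Endothelial genes had 1 of 15 called, Emcn at log2 0.46, and 3 adjusted over the list alone (camera adjusted p = 0.000184, adjusted p = 0.433 with an estimated correlation). The 40 cell cycle genes had 0 called and 14 adjusted over the list alone, with a median log2 difference of 0.56 (camera adjusted p = 5.4e-07, adjusted p = 0.523 with an estimated correlation). In the interferon list Bst2 alone of 19 rose over all genes (18.5 to 44.8 CPM), with 2 adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.661 with an estimated correlation). Skeletal muscle genes had 0 of 21 called, and their summed CPM was 1822 in WT placebo 2 against 61.9 in WT placebo 1 (camera adjusted p = 0.026 downward, adjusted p = 0.833 with an estimated correlation). Without WT placebo 2 the interferon and muscle lists both changed direction, and over 14 other fits their adjusted p reached 0.885 and 0.355.

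In edgeR 225 of 14531 genes were called for estradiol in WT, 95 higher and 130 lower, and the authors' deposited table lists 497 at an adjusted p under 0.05. The balance turned without WT estradiol 3 (105 higher and 85 lower) and in limma-voom (60 and 56). Without WT estradiol 1 the count was 113 and without WT estradiol 2 it was 131. Of 30 called genes named by the rule, 12 kept their call under every alternative (Greb1, Asb4, Lgi2, Shank2, Myo5c, Trpc6, Pi15, Prss34, St8sia2, Wnt4, Sost and Bst2). The adjusted p of Igf1 ranged from 2.03e-08 to 0.0712, that of Lox to 0.0503 without WT placebo 1, that of Sftpa1 to 0.0654, and that of Vpreb3 to 0.26, and Acp5, Ocstamp, Emcn, Lum, Wif1 and Wnt16 lost their calls in 4 to 9 alternatives each. The 12 lists that passed became 6 without WT placebo 2, which held the high muscle level, and 7 without WT estradiol 3. The adjusted p reached 0.319 for the fibrous matrix, 0.242 for the collagen processing, 0.154 for the growth hormone and IGF, 0.567 for the Wnt and 0.119 for the endothelial list.

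**Figure D2:**
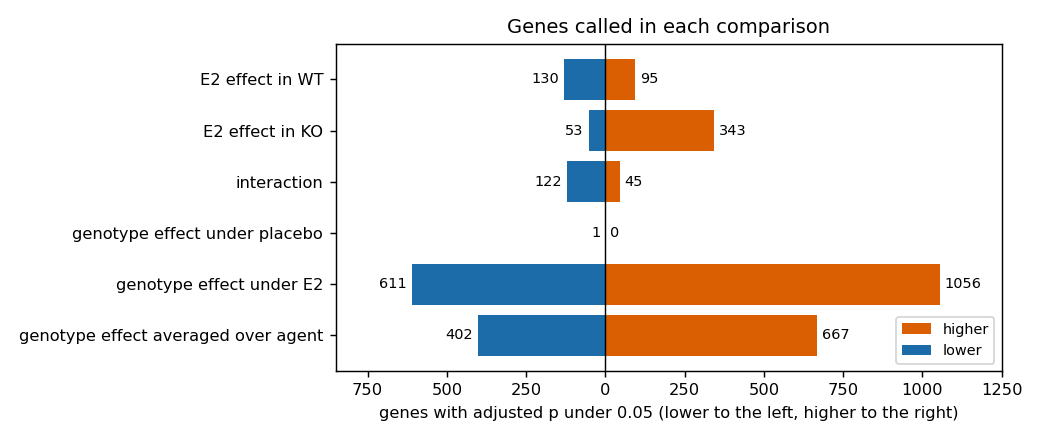
Numbers of genes called at an adjusted p under 0.05 in the 6 comparisons, drawn to the right of 0 where higher and to the left where lower. Under estradiol 1056 genes were higher and 611 lower in KO than in WT, while under placebo 0 were higher and 1 was lower.

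The same treatment was then compared in animals without the receptor, to see what estradiol changes there. Of 40 cell cycle genes 30 rose in KO tissue, and adjusted over the list alone 37 were higher and 1 was lower, with a median log2 change of 1.16 (camera adjusted p = 3.36e-37, adjusted p = 0.159 with an estimated correlation). Mki67, a marker of dividing cells, rose from 60.0 ± 4.4 to 166 ± 24 CPM (n = 3 and 3, log2 1.47, SE 0.20, adjusted p = 0.00562). Rrm2, which makes DNA precursors, rose from 25.6 ± 0.73 to 61.5 ± 11 CPM (log2 1.26, SE 0.12, adjusted p = 0.000866). Top2a, Kif11 and Birc5, genes of chromosome handling and division, rose by 1.40, 1.47 and 1.17 on the log2 scale. Summed cell cycle CPM was 987 ± 58 under placebo and 1817 ± 246 after estradiol.

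The neutrophil, B lineage and erythroid lists ranked higher in KO by camera at its preset correlation. Summed neutrophil lineage CPM was 327 ± 417 in KO placebo, with 1.61 in KO placebo 1, and 2705 ± 1967 in KO estradiol. Of 15 neutrophil genes 1 rose, Fcnb (log2 4.19, SE 0.89, adjusted p = 0.047), with 2 adjusted over the list alone (camera adjusted p = 9.08e-12, adjusted p = 0.328 with an estimated correlation). Summed B lineage CPM went from 197 ± 70 to 359 ± 101. Blnk rose (log2 0.78, SE 0.16) as 1 of 16 B lineage genes, with 6 adjusted over the list alone (camera adjusted p = 7.56e-07, adjusted p = 0.359 with an estimated correlation). Erythroid genes had 0 of 10 called over all genes (camera adjusted p = 0.00216 upward, adjusted p = 0.453 with an estimated correlation). The protease gene Prss34, typical of basophils, had 3 counts in all over the KO placebo libraries and 3.32 ± 1.0 CPM after estradiol, a ratio of 73.6 with a counting interval of 24.8 to 360. Skeletal muscle genes summed to 619 ± 451 CPM in KO placebo (712 and 1016 in samples 1 and 2) and 29.2 ± 1.7 in KO estradiol, with 0 of 21 called over all genes and 17 adjusted over the list alone (camera adjusted p = 0.000194, adjusted p = 0.472 with an estimated correlation).

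The number of genes lower with estradiol in KO depended on method and library, with 53 in edgeR, 261 in DESeq2, 375 in limma-voom and 401 in the authors' deposited table. In edgeR it was 5, 4 and 84 without KO placebo 1, 2 and 3, and 25, 6 and 23 without KO estradiol 1, 2 and 3. Plin4, a lipid droplet protein, fell by 4.98 on the log2 scale (SE 0.99), Wnt10a by 1.57 (SE 0.36) and Gpnmb from 76.0 to 38.1 CPM (adjusted p = 0.0351). Dlx5, an osteoblast transcription factor, fell by 0.55 on the log2 scale (SE 0.12) as the 1 called gene of 16 in the osteoblast list (camera adjusted p = 0.000194, adjusted p = 0.293 with an estimated correlation). Junb fell by 0.50 on the log2 scale as the 1 called gene of 18 in the immediate early list, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0087, adjusted p = 0.453 with an estimated correlation). The TGF-beta, Wnt, protease, endothelial and fibrous matrix lists also ranked lower, at camera adjusted p values of 0.000473, 0.00423, 0.00946, 0.00227 and 0.0358, with adjusted p values of 0.293, 0.293, 0.293, 0.417 and 0.453 with an estimated correlation. The interferon list ranked higher (camera adjusted p = 0.0405, adjusted p = 0.576 with an estimated correlation). Without KO placebo 3 the immediate early (adjusted p up to 0.418), protease (up to 0.0929), fibrous matrix and interferon lists lost their calls. The last 2 also lost them without KO estradiol 2 or 3, with adjusted p up to 0.182 and 0.368, and the interferon list without WT placebo 2. Igf1 at log2 0.24 (adjusted p = 0.542), Wnt4 at -0.23 (adjusted p = 0.19) and Prg4, the joint lubricant, at -1.14 (SE 0.39, adjusted p = 0.193) did not pass. Greb1 stayed near the floor at 0.0847 and 0.0570 CPM.

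In edgeR 396 genes were called for estradiol in KO, 343 higher and 53 lower, and the authors' deposited table lists 1074. With the replicate number as a block edgeR called 629, 542 higher and 87 lower, with Cebpe, Prtn3, Vpreb3, Pax5 and Pou2af1 of the neutrophil and B lineage lists among the higher. The count was 105 without KO placebo 1, 139 without KO placebo 2, 241 without KO placebo 3, 126 without KO estradiol 2, and 134 without WT placebo 2 and KO placebo 1 together, a pair chosen after the data were seen. Prss34, Rrm2, Top2a, Kif11, Birc5 and Mki67 kept their calls under every alternative, and the other 18 of the 24 called genes named by the rule lost theirs in at least 1 fit without a library, with adjusted p reaching 0.139 for Fcnb, 0.105 for Plin4 and 0.117 for Blnk.

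**Figure D3:**
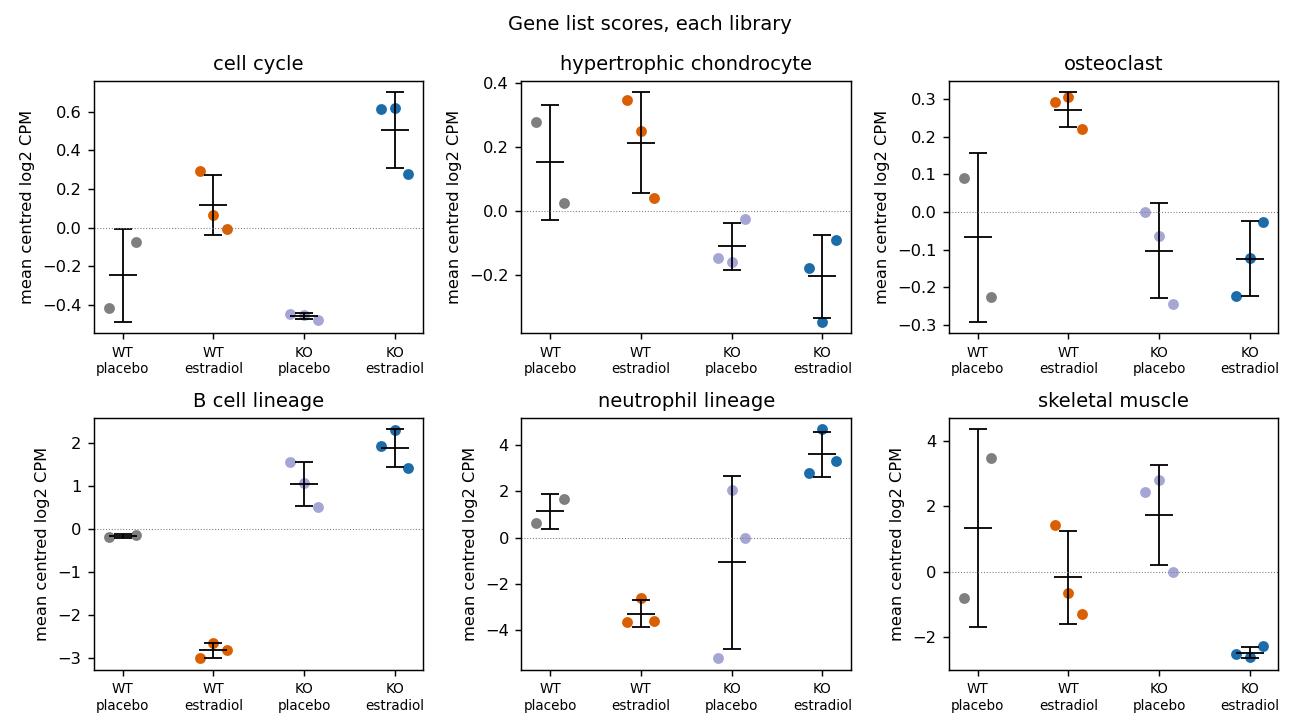
Mean centred log2 CPM of the members of 6 gene lists (vertical axis) in each library, with lines for the group mean ± SD. Summed CPM of the cell cycle list is 1817 in KO estradiol and 987 in KO placebo, and that of the B lineage list is 26.3 in WT estradiol and 359 in KO estradiol.

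Whether estradiol acted differently in the 2 genotypes was tested as an interaction. Some of the genes that estradiol raised in WT had a higher effect there than in KO, among them Trpc6 (interaction log2 4.22, SE 0.27, adjusted p = 3.06e-05), Lgi2 (adjusted p = 0.000669), Asb4 (adjusted p = 0.00177) and Shank2 (adjusted p = 0.00358). A2m differed by 2.92 on the log2 scale (SE 0.33, adjusted p = 0.00177), as its KO change was -0.22 (adjusted p = 0.748). Sost differed by 1.58 (SE 0.19, adjusted p = 0.00177), the 1 called gene in the osteoblast list, with 3 adjusted over the list alone. Igf1 differed by -1.49 (SE 0.26, adjusted p = 0.0201), lower after estradiol in WT alone. Rrm2 (log2 -1.21, adjusted p = 0.00491) and Uhrf1 (log2 -1.33, adjusted p = 0.0285) were the 2 cell cycle genes called, with 16 adjusted over the list alone, and their difference points to a greater rise in KO.

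Tmprss3 and Prss34 moved in opposite directions in the 2 genotypes. Tmprss3 stood at 0.615 and 0 CPM in WT placebo and estradiol, and at 1.07 and 5.07 CPM in KO (adjusted p = 0.00358). Prss34 stood at 3.25, 0, 0.0469 and 3.32 CPM in the same order (adjusted p = 0.00106). Of 16 B lineage genes 7 were called, with 13 adjusted over the list alone, among them Vpreb3 (adjusted p = 0.00177) and Pax5 (adjusted p = 0.0182). Of 15 neutrophil genes 1 was called and 14 adjusted over the list alone. In the T and NK cell list, with 8 of 16 genes tested, 2 were called, Il7r (adjusted p = 0.0103) and Nkg7 (adjusted p = 0.0114). In the endothelial list Egfl7 was called (log2 0.60, adjusted p = 0.0438), with 5 adjusted over the list alone, and in the osteoclast list 0 of 15 were called, with 6 adjusted over the list alone. Cell cycle (camera adjusted p = 5.12e-14), neutrophil (5.12e-14), B lineage (2.14e-12), endothelial (1.18e-07) and osteoclast (9.58e-08) lists passed in all 14 other fits of the preset test, and all 12 lists that passed had adjusted p values of 0.377 to 0.852 with an estimated correlation.

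Across all genes, the log2 effects of estradiol in WT and in KO, which share no library, had a Pearson r of -0.0064 and a Spearman rho of 0.169, and genes are not independent replicates. Without WT placebo 2 the Pearson r was -0.220, and without KO estradiol 2 it was 0.112. The Spearman rho fell to 0.0163 without WT placebo 1, and lay between 0.139 and 0.185 without any other single library. There were 22 genes called in both genotypes, with 4 higher in both, 6 lower in both and 12 lower in WT but higher in KO. Independent lists of these sizes would share 2.24, 0.474 and 3.07. The 4 genes higher in both, named because they are few, were Hmmr, Cdca2, Troap and Kif20b, all genes of mitosis. Myb, a progenitor cell transcription factor chosen after its values were seen, was among the 12, at log2 -4.84 in WT and 1.51 in KO.

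In edgeR the interaction was called for 167 genes, 45 with the higher WT effect and 122 with the lower. With the replicate number as a block edgeR called 301, 55 higher and 246 lower, and DESeq2 called 561, 140 and 421. The directions were nearer to even in limma-voom (40 and 47) and without WT placebo 1 (61 and 81). The count was 71 without WT placebo 2, 68 without WT estradiol 1, 85 without WT estradiol 2, 100 without KO placebo 1, 270 without KO estradiol 1, and 56 without WT placebo 2 and KO placebo 1. Lgi2, Asb4, Shank2, Trpc6, Prss34, Tmprss3, Bfsp2 and Sost kept their calls under every alternative. The adjusted p reached 0.201 for Igf1, 0.0633 for Rrm2, 0.118 for Uhrf1, 0.107 for Egfl7, 0.188 for Vpreb3, 0.214 for Pax5, 0.148 for Il7r and 0.137 for Nkg7.

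**Figure D4:**
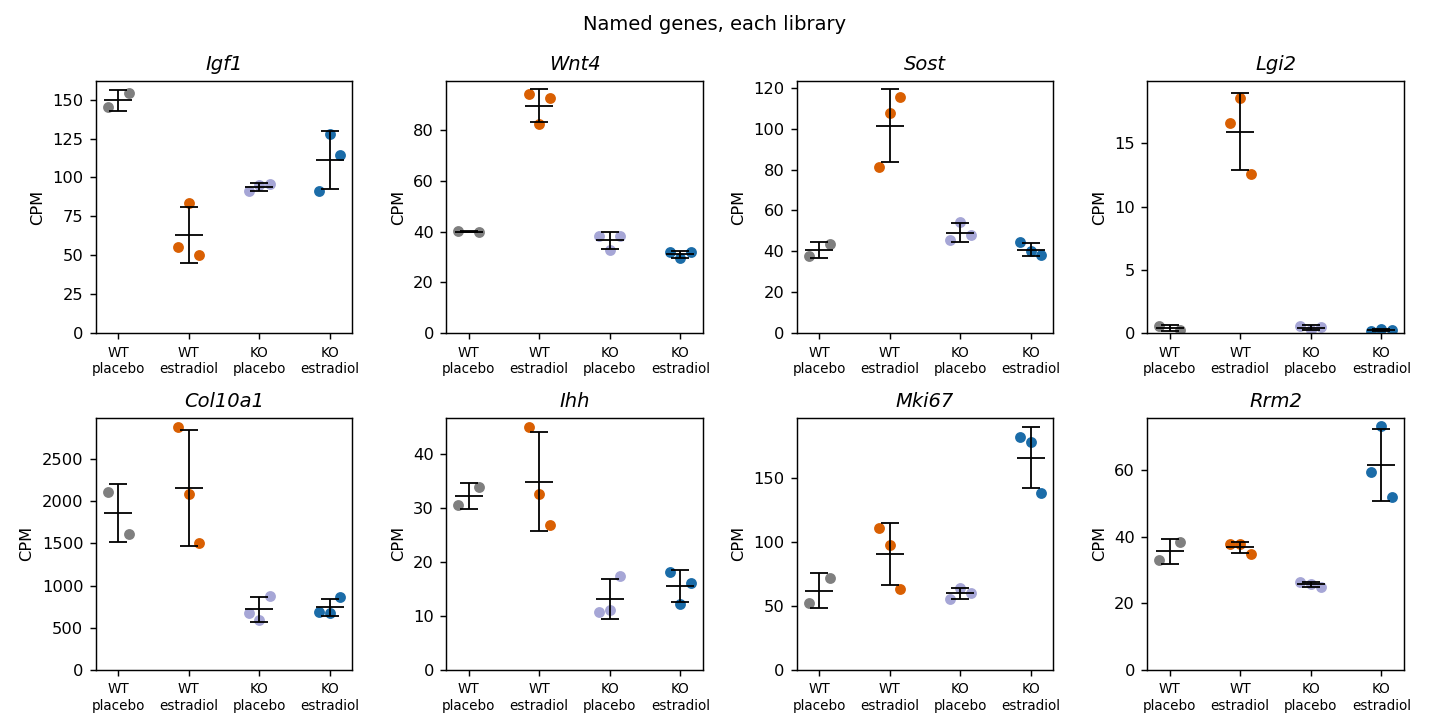
Expression in CPM (vertical axis) of Igf1, Wnt4, Sost, Lgi2, Col10a1, Ihh, Mki67 and Rrm2 in each library, with 1 point per library and lines for the group mean ± SD. Igf1 lies at 63.0 CPM in WT estradiol and at 94.0 to 150 CPM in the other groups, and Col10a1 at 1861 and 2158 CPM in WT against 716 and 739 CPM in KO.

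Loss of the receptor without estradiol was examined in the placebo groups. A2m was the 1 gene called, 9.12-fold lower in KO at 2.85 ± 0.43 CPM (n = 3) than in WT at 26.1 ± 4.0 CPM (n = 2), with a log2 difference of -3.19 (SE 0.23, adjusted p = 0.000352), and it stayed called under every alternative. The next smallest p values belonged to C430049B03Rik (log2 -1.20, adjusted p = 0.118), Prss34 (adjusted p = 0.118), Smim5 (log2 -0.94, adjusted p = 0.127) and Mcpt8 (adjusted p = 0.127), which did not pass. Col10a1, the collagen of hypertrophic cartilage, stood at 1861 ± 348 CPM in WT and 716 ± 148 in KO (adjusted p = 0.348), and Ihh at 32.2 and 13.1 CPM (adjusted p = 0.387).

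By list under placebo, cartilage (0 of 26 called, 2 adjusted over the list alone, camera adjusted p = 0.000199), hypertrophic (3 adjusted over the list alone, 0.00707), hypoxia (4 adjusted over the list alone, 0.00117), cell cycle (0.000199), neutrophil (2.66e-05), macrophage (0.00695) and interferon (1 adjusted over the list alone, 0.000826) genes ranked lower in KO. TGF-beta (0.00707), immediate early (0.0213) and B lineage genes ranked higher, the last with 0 of 16 called and 12 adjusted over the list alone (1.28e-07). All 10 of these lists had an adjusted p = 0.545 with an estimated correlation, and the B lineage list alone of them passed under all 14 other fits of the preset test. Summed B lineage CPM was 81.6 ± 5.8 in WT and 197 ± 70 in KO. The neutrophil list was lost without KO placebo 1 and with the replicate number as a block, with adjusted p up to 0.756, and it changed direction without WT placebo 2 and KO placebo 1 together. The cell cycle list was lost without WT placebo 2 (up to 0.331), and the TGF-beta list without WT placebo 2 or KO placebo 3 (up to 0.143). The cartilage, hypertrophic, macrophage, interferon, hypoxia and immediate early lists were lost without WT placebo 1, the last 2 also without KO placebo 3, with adjusted p reaching 0.743 for cartilage and 0.717 for hypertrophic genes. In edgeR 1 gene was called and 1338 had an unadjusted p under 0.05, against 50 called without WT placebo 1, 2 without KO placebo 3, 40 in DESeq2 and 36 in the authors' deposited table.

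The same genotype contrast under estradiol asked what differs when the hormone is present. Some of the genes that estradiol raised in WT were lower in KO. A2m was at 170 ± 43 CPM in WT and 2.41 ± 0.53 in KO (n = 3 and 3, log2 -6.11, SE 0.23, adjusted p = 1.81e-07), and Trpc6 was 26.3-fold lower (adjusted p = 5.76e-08). Greb1 was at 3 counts in all of KO, a ratio of 230 in favour of WT with a counting interval of 78.6 to 1119. Lgi2, Asb4, Myo5c and Pi15 differed by -5.99, -5.18, -4.45 and -3.96 on the log2 scale. In the hypertrophic list 6 of 14 genes were lower in KO, among them Col10a1 (log2 -1.55, SE 0.23, adjusted p = 0.00256), Ibsp, a mineral-binding protein (log2 -1.12, SE 0.12), Ihh (log2 -1.17, SE 0.23) and the parathyroid hormone receptor Pth1r (log2 -0.57, SE 0.10). That list ranked lower at a camera adjusted p = 0.000198 (adjusted p = 0.502 with an estimated correlation). In the cartilage matrix list 1 of 26 was higher, Matn4 (log2 1.01, SE 0.16), and 1 was lower, Matn1 (camera adjusted p = 0.000585 downward, adjusted p = 0.657 with an estimated correlation). Igf1 was higher in KO (log2 0.82, SE 0.17, adjusted p = 0.0125).

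Osteoclast genes were lower in KO in 8 of 15 members, and in 11 adjusted over the list alone, with Acp5 at log2 -0.82 (SE 0.10), Ocstamp at -0.73 and Dcstamp at -0.62 (camera adjusted p = 6.72e-08, adjusted p = 0.468 with an estimated correlation). Macrophage genes were lower in 9 of 15, with 9 lower and 2 higher adjusted over the list alone, among the lower Cd68 (log2 -0.58) and C1qc (log2 -0.96; camera adjusted p = 3.09e-05, adjusted p = 0.468 with an estimated correlation). Endothelial genes were lower in 5 of 15, and in 10 adjusted over the list alone, among them Emcn (log2 -0.61) and Egfl7 (log2 -0.58; camera adjusted p = 4.82e-07, adjusted p = 0.468 with an estimated correlation). Collagen processing genes were lower in 3 of 23, with 7 adjusted over the list alone, led by Loxl1 at log2 -0.46 (camera adjusted p = 1.85e-05, adjusted p = 0.502 with an estimated correlation). Hypoxia genes were lower in 3 of 18, with 5 adjusted over the list alone, led by Adm at log2 -1.15 (camera adjusted p = 0.0014, adjusted p = 0.502 with an estimated correlation). Bst2 was lower (log2 -1.45) as the 1 called gene of 19 in the interferon list (camera adjusted p = 0.00496, adjusted p = 0.657 with an estimated correlation).

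All 16 B lineage genes were higher in KO under estradiol, with Rag1, an enzyme of receptor gene assembly, at 0.0745 CPM in WT and 40.8 in KO (camera adjusted p = 1.83e-12, adjusted p = 0.468 with an estimated correlation). Neutrophil genes were higher in 11 of 15, and in 15 adjusted over the list alone (camera adjusted p = 2.29e-06, adjusted p = 0.502 with an estimated correlation). Erythroid genes were higher in 3 of 10, with 9 adjusted over the list alone (camera adjusted p = 0.00723, adjusted p = 0.657 with an estimated correlation). Of 16 genes in the T and NK cell list 8 could be tested and 4 were higher, among them Il7r at log2 5.52 (camera adjusted p = 0.0274, adjusted p = 0.502 with an estimated correlation). Whether that list moved apart from the B lineage genes was not tested. Cell cycle genes were higher in 11 of 40, with 12 adjusted over the list alone, among them Rrm2 (log2 0.74, SE 0.11), Uhrf1 (log2 1.12) and Mki67 (log2 0.87, SE 0.20; camera adjusted p = 2.14e-07, adjusted p = 0.502 with an estimated correlation). Tmprss3 and Prss34, with 0 counts in WT estradiol, were at least 40.0-fold and at least 26.2-fold higher in KO.

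In edgeR 1667 genes were called, 1056 higher and 611 lower in KO, and the authors' deposited table lists 1959. The count was 976 without WT estradiol 1, 919 without WT estradiol 3, 867 without KO estradiol 2 and 1072 without KO estradiol 3, and 41 of 63 called genes named by the rule kept their call under every alternative. Igf1 lost its call without WT estradiol 1 or 3 (adjusted p up to 0.0516), Mki67 without KO estradiol 1 or 2 (up to 0.0654) and Matn1 in 5 such fits (up to 0.0801), and the T and NK list lost its call without WT estradiol 1 or 2 (up to 0.0799) and the interferon list without WT estradiol 3 or KO estradiol 1 (up to 0.139).

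The genotype difference averaged over both agents set 6 KO samples against 5 WT samples. A2m was lower in KO by 4.65 on the log2 scale (SE 0.16, adjusted p = 1.37e-07). Hypertrophic cartilage genes were lower in 4 of 14 members, and in 7 adjusted over the list alone: Col10a1 (log2 -1.46, SE 0.17, adjusted p = 0.00119), Ihh (log2 -1.23, SE 0.17, adjusted p = 0.00244), Ibsp (log2 -0.82, SE 0.09) and Pth1r (log2 -0.40). That list passed at a camera adjusted p = 0.000238 (adjusted p = 0.51 with an estimated correlation). In the cartilage matrix list Matn4 was higher (log2 0.59), 2 members including Ucma (log2 -1.84) were lower, and 9 were lower adjusted over the list alone (camera adjusted p = 5.36e-05, adjusted p = 0.619 with an estimated correlation). Col2a1, the main cartilage collagen, stood at log2 -0.88 (SE 0.29, adjusted p = 0.0948).

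All 16 B lineage genes were higher in KO on average, with Pax5 at log2 3.23 and Vpreb3 at 4.16 (camera adjusted p = 3.02e-14, adjusted p = 0.51 with an estimated correlation). Spib, a B cell and dendritic cell factor, stood at 13.4 and 0.511 CPM in WT placebo and estradiol and at 35.9 and 69.6 CPM in KO (log2 4.25, SE 0.46). Osteoclast genes were lower in 5 of 15, with 9 adjusted over the list alone (Acp5 log2 -0.47; camera adjusted p = 9.82e-06, adjusted p = 0.51 with an estimated correlation), and macrophage genes in 7 of 15, with 9 adjusted over the list alone (Cd68 log2 -0.39; camera adjusted p = 4.69e-05, adjusted p = 0.51 with an estimated correlation). Hypoxia genes were lower in 4 of 18, with 8 adjusted over the list alone (Adm log2 -1.02; camera adjusted p = 0.000238, adjusted p = 0.51 with an estimated correlation), and endothelial genes in 3 of 15, with 6 adjusted over the list alone (camera adjusted p = 0.000238, adjusted p = 0.51 with an estimated correlation). Bst2 was lower by 0.95 on the log2 scale as 1 interferon gene of 19 (camera adjusted p = 0.000239, adjusted p = 0.619 with an estimated correlation), and collagen processing genes were lower in 2 of 23 (camera adjusted p = 0.000427, adjusted p = 0.619 with an estimated correlation). Erythroid genes were higher in 1 of 10, with 9 adjusted over the list alone (camera adjusted p = 0.0228, adjusted p = 0.687 with an estimated correlation). Neutrophil genes had 0 of 15 called over all genes in edgeR and 9 adjusted over the list alone (camera adjusted p = 0.00697, adjusted p = 0.687 with an estimated correlation). The erythroid list lost its call without WT placebo 1, WT estradiol 2 or KO placebo 2 (adjusted p up to 0.118) and the interferon list without WT placebo 1 (0.142).

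In edgeR 1069 genes were called in the average, 667 higher and 402 lower in KO, and for genes whose genotype difference depends on the agent the average describes neither group. The count was 1711 without WT placebo 1, 408 without WT placebo 2, 665 without WT estradiol 1, 579 without KO placebo 1, 466 without KO placebo 2, 700 without KO estradiol 2, 671 without KO estradiol 3, and 265 without WT placebo 2 and KO placebo 1, and of 46 called genes named by the rule 23 kept their call under every alternative, Ucma (up to 0.0705 without WT placebo 1), Matn4 (up to 0.087) and Adm (up to 0.0546) not among them.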

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

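Of the tests in this part, those of the interaction of genes near Esr1, of the neutrophil and B lineage, erythroid and muscle levels against the cell cycle genes, the counts over other splits of the samples, and the spread over the WT libraries alone, were chosen after the result was seen. Those of the share of genes near Esr1 and of the megakaryocyte markers were written down before their own values were seen. The megakaryocyte markers were not among the gene lists fixed before the data were examined. Their check addresses the lower B and neutrophil lineage genes with estradiol in WT, a pattern that had already been seen.

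The estradiol effect differed between genotypes for 167 genes by the edgeR interaction test. Of the genes it raised in WT, Trpc6 (adjusted p = 3.06e-05), Lgi2 (0.000669), Asb4 (0.00177), Pi15 (0.00337), Shank2 (0.00358), Sftpa1 (0.00737), Greb1 (0.021) and Myo5c (0.0446) had a higher effect in WT. The adjusted p reached 0.0547 for Pi15, 0.112 for Sftpa1, 0.299 for Greb1 and 0.266 for Myo5c over the alternatives, with Greb1 and Myo5c lost without WT placebo 2 and 5 or more other settings. Genes with the lower effect in WT, several of them of blood lineages, included Prss34 (0.00106), Tmprss3 (0.00358), Bfsp2 (0.00737), Nkg7 (0.0114), Cecr2 (0.0132), Prss57 (0.0216), Ms4a3 (0.0356) and Fcnb (0.0356). Ms4a3 and Fcnb lost their calls in 10 of 20 alternatives each, and the adjusted p reached 0.107 for Prss57, 0.137 for Nkg7 and 0.321 for Cecr2.

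The camera interaction test also singled out lists. Cell cycle (5.12e-14), neutrophil (5.12e-14), B lineage (2.14e-12) and T and NK cell (0.0213) lists had the lower effect in WT. Osteoclast (9.58e-08), endothelial (1.18e-07), collagen processing (0.000489), macrophage (0.0115), osteoblast (0.0121), muscle (0.0121), hypertrophic (0.0369) and immediate early (0.0481) lists had the higher effect in WT. Of 14 other fits the immediate early list lost its call in 9 (adjusted p up to 0.306), the hypertrophic in 6 (0.495), T and NK in 5 (0.0904), osteoblast in 3 (0.363), muscle in 2 (0.729), macrophage in 2 (0.144) and collagen processing in 1 (0.0559), without KO estradiol 2. With an estimated correlation (adjusted p 0.377 to 0.852) or in fry 0 of the 12 lists passed.

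With estradiol in WT 7 of 16 B lineage genes were lower and the neutrophil list, with 0 of 15 called in edgeR and 6 adjusted over the list alone, ranked lower by camera at its preset correlation (adjusted p = 0.59 with an estimated correlation), while under estradiol 16 of 16 and 11 of 15 such genes were higher in KO than in WT. Less marrow in the dissected WT tissue is a candidate explanation, and megakaryocyte markers, 12 of 12 tested, offer a check from another marrow lineage. They changed by -1.40 in mean log2 CPM where a fall of at least -1.34 was needed, against -2.67 (SE 0.35) for the B lineage list, with an SE of 1.02 over all libraries, widened by KO estradiol (SD 2.09), and of 0.13 over the WT libraries alone. The fall lies beyond the WT spread, as less marrow needs. However, the mean log2 CPM of these markers was -1.32 in KO placebo, near the -1.44 of WT estradiol. Summed B lineage CPM was 197 in KO placebo against 81.6 in WT placebo, so the markers did not follow it across groups. The erythroid list changed by 0.07 (SE 0.20 over the WT libraries), but its members by log2 -3.47 to 3.01. Its summed CPM went from 10.9 to 24.1, but most of that sum in both groups came from Alas2, a gene of red cell haem synthesis. Of its 10 tested members 4 had a positive log2 change, with a median of -0.35, so the sum does not show a rise of the lineage. The 4 megakaryocyte markers most abundant in WT placebo also differed. Gp1bb went from 8.80 to 8.15, Pf4 from 5.94 to 7.46, Itga2b from 4.91 to 2.61 and Ppbp from 4.33 to 0.242 CPM. Less marrow and a change in the lineages themselves thus cannot be told apart. An effect of estradiol on these cells through the receptor stays open and was not tested.

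Cell cycle genes were higher with estradiol in KO, with a summed difference of 830 CPM (SE 133). With the summed neutrophil and B lineage CPM in the model the difference was 515 CPM (SE 172), above 0 by more than 2 SE. The model left 5 residual degrees of freedom, and marker sums may not measure these cells in full. More neutrophil and B lineage cells are therefore not excluded as the cause. A part may come with B lineage cells (slope 1.80, SE 0.80). More erythroid cells are argued against as far as the erythroid sum measures them, as 857 CPM (SE 182, 6 residual degrees of freedom) remained. Muscle RNA in the KO placebo libraries is argued against, since the mean log2 difference was 0.96 (SE 0.13) and became 1.23 (SE 0.17) with the muscle level in the model. An action of estradiol without receptor alpha on dividing cells of the tissue stays open and was not tested.

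Of the 1069 genes called between genotypes in the average over agents, some could differ through DNA from the donor strain around the targeted Esr1 locus, and of the 1004 with a matched position 0.598% (6) lay within 20 Mb of Esr1, against 0.597% (75 of 12561) of other tested genes (Fisher's exact test, one-sided p = 0.56). Of the 6, a constant difference between alleles as the whole cause is argued against by the interaction log2 difference for Myb (-6.35, SE 0.54), Akap12 (-1.38, SE 0.31) and Ipcef1 (-3.61, SE 0.85), for Map7 (-0.41, SE 0.38), Shprh (0.00212, SE 0.17) and Tab2 (-0.091, SE 0.10) donor DNA and receptor loss cannot be told apart, and called genes without a matched position were not tested. The count of 1069 was reached by 1 of 100 splits drawn within agent, the real one. The highest other, 1021, kept the real WT estradiol group and took WT placebo 2 and KO placebo 3 as WT. Other splits that kept that group called 383, 321 and 102. The count thus follows the estradiol samples in large part, and these splits cannot show a genotype difference that holds under both agents. For KO estradiol against KO placebo, 1 of 10 splits reached the real 396 and the highest other was 1 (0 in the other 3 that part all same-number pairs), and for genotype under estradiol 1 of 10 reached the real 1667 and the highest other was 0, but 10 splits are too few for a share under 0.05. A biological effect of receptor loss stays open, as untested beyond these comparisons.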

How the results depend on the processing

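The fits without Rn45s and without WT placebo 2 and KO placebo 1 were added after the data were seen, the others before. Of 7456 settings over named genes, 6786 stayed on their side of the threshold, 485 lost a call, 185 gained one and 0 reversed, and 91 uncalled values changed sign. The 6786 include genes that were not called in either fit. Of the called named genes, 18 of 30 for estradiol in WT, 18 of 24 in KO and 18 of 26 for the interaction lost their call somewhere. So did 22 of 63 for genotype under estradiol and 23 of 46 in the average. The lower Esr1 level in KO was called in every fit, from -0.95 without WT placebo 1 to -1.45 without WT placebo 2 among single removals. The scaling changes and the removal of Rn45s moved no count by over 1.5 times. The cause was not tested for any change below, except that a stricter or looser threshold passes fewer or more genes by construction.

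At least a 2-fold change left 128 genes for estradiol in WT, 210 in KO, 646 for genotype under estradiol and 241 in the average. An adjusted p under 0.1 gave 448, 714, 395 (interaction), 2512 and 2295. DESeq2 called 656 in WT, 952 in KO, 561 for the interaction, 40 for genotype under placebo and 1937 in the average. Limma-voom with quality weights called 116, 1032 and 87 for WT, KO and interaction. A fit of the KO groups alone called 226. Without WT placebo 2 and KO placebo 1, the counts were 134 in KO, 56 for the interaction, 1528 for genotype under estradiol and 265 in the average, and 6 lists passed in WT.

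Leaving out 1 library at a time gave 113 to 280 genes for WT, 105 to 505 for KO, 68 to 270 for the interaction, 1 to 50 for genotype under placebo, 867 to 1368 under estradiol and 408 to 1711 in the average. Lists passing ranged from 6 to 12 in WT and 7 to 13 for the interaction. The Pearson r between the 2 estradiol effects ranged from -0.220 to 0.112, with -0.163 without KO placebo 2. Their Spearman rho ranged from 0.0163, without WT placebo 1, to 0.185. With an estimated correlation 0 lists passed in each of the 6 comparisons, against 12, 13, 12, 10, 13 and 11 with the preset one. Fry passed 0 in WT, 0 for the interaction, 0 under placebo, 2 in KO, 7 under estradiol and 7 in the average. In KO these were the cell cycle and epithelial lists. Under estradiol and in the average they were the B lineage, endothelial, osteoclast, macrophage, hypertrophic, epithelial and estrogen-responsive lists. The epithelial and estrogen-responsive lists did not pass by camera in those comparisons.

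With the replicate number as a block, the counts were 629 for KO, 301 for the interaction and 17 for genotype under placebo, 257 in WT, 1799 for genotype under estradiol and 1533 in the average, and r was -0.0892.

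Depth limits the genes with the largest rises, since a level of 3 counts is 0.118 to 0.204 CPM and Greb1, Sftpa1, Prss34 and Tmprss3 lie at or below it in some groups.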

Other observations

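Marker genes of rarer blood cells were chosen after the data were examined. Of 5 tested basophil and mast cell genes, Mcpt8 and Prss34 passed with estradiol in both genotypes, and Cpa3 (adjusted p = 0.0741 in WT and 0.406 in KO), Ms4a2 (0.157 and 0.133) and Gata2 (0.896 and 0.798) passed in neither. Mcpt8 stood at 1.42 CPM in WT placebo, 0 in WT estradiol, 0.0298 in KO placebo and 1.66 in KO estradiol (adjusted p = 0.00377 in WT and 0.00562 in KO). The eosinophil gene Prg2 stood at 92.0 ± 92, 1.48 ± 1.7, 47.9 ± 58 and 187 ± 132 CPM in the same order. Epx stood at 14.7 ± 13, 0.0658 ± 0.11, 9.52 ± 10 and 38.3 ± 23 CPM. The estradiol contrast passed for neither gene in either genotype. Alas2, the first enzyme of red cell haem synthesis, stood at 7.82, 21.6, 9.30 and 38.3 CPM.

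Libraries stood apart within groups. The muscle list summed to 1822 CPM in WT placebo 2 and 61.9 CPM in WT placebo 1. Neutrophil lineage CPM was 1.61 in KO placebo 1 and 797 in KO placebo 2. KO estradiol 2 held the highest neutrophil lineage sum, 4968 CPM, and the highest erythroid sum, 258 CPM. The first principal component held 40.2% of the variance and the next held 20.2%.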
